A study of Caenorhabditis elegans with 8 samples.

How the data were processed

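Whole-animal RNA of the C. elegans wild-type strain N2 was sequenced in 8 libraries, 4 from animals on Pseudomonas aeruginosa PA01 and 4 from animals on Escherichia coli OP50. Per the labels, worms were maintained at 20 °C, bacteria grew on PGS plates for 24 h at 37 °C and 24 h at 25 °C, and mid-L4 animals were exposed for 12 h at 25 °C. Libraries were made from 3 µg of total RNA. The labels do not state whether the libraries keep the strand. Per the submitters' processing notes, reads were mapped to the genome build WBcel235 with Bowtie2 2.2.3 and TopHat2 2.0.12 and counted with HTSeq 0.6.1.

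The deposited values are RPKM, computed by the authors as reads per kilobase of the listed gene length with the reads over the listed genes scaled to a common total. The 8 files list the same 27593 genes. Each value times the gene length was checked to be a whole number of reads within 0.001 reads in 100% of values, so depth could be worked back: 15262523 to 32243426 reads per library. Of the lengths of protein-coding genes 93.9% are multiples of 3, so most are coding lengths. Of the listed genes 24898 (90.2%) were matched to the annotation of Ensembl release 115 for symbols, biotypes and positions, and the mitochondrial genome list was taken as the 12 protein-coding genes on that chromosome. Floors and depths cover counting error only.

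Values were used as deposited, with no further scaling, as log2(RPKM + 1). Genes at 1 RPKM or more in at least 4 of the 8 libraries were tested, 14885 in all, with limma 3.58.1 (lmFit and eBayes with trend and robust) in R 4.3.3. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and genes at 2-fold or more were also counted. The test, the 55 gene lists, the other settings and the rule for the genes named were chosen before the data were examined. The lists were tested with camera, with a preset correlation of 0.01, against all other tested genes, with an estimated correlation and fry beside it, and adjusted over the lists. Gene classes with 8 or more tested members were tested by a one-sided Fisher's exact test, adjusted over 151 classes and both directions, among tested genes with a class symbol (7082). The named genes are fixed markers and the 8 largest rises and 8 largest falls among called genes with separated groups and at least 5 RPKM in the higher group. They also hold, for each list, up to 4 called members with the largest change and at least 5 RPKM in the higher group. For lists without such a called gene they hold up to 2 members with the highest mean. For each enriched class not covered by a list they hold up to 2 called members with the largest change. F22B8.7, str-7, K10D11.6 and col-137 were named after their values were seen.

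The other settings fixed beforehand were median-ratio scaling, quantile normalization, every gene above 0 in at least 1 library, a mean of 5 RPKM or more, pseudocounts of 0.1 and 0.5, limma without trend and robust, the replicate number as a block, and leaving out each library. Alternatives added after seeing the data were limma voom on the recovered reads, protein-coding genes alone, the adult-stage score as a covariate, and the enrichment of gene classes under the settings used for the other counts. A count model on the recovered reads was planned and was not run, by a choice of procedure and not a limit of the data, and limma voom was run on those reads in its place. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.

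The procedure was tested on simulated data with the real genes, lengths and depths of the PA01 versus OP50 comparison, in which 200 genes were changed. Of the changed genes that passed the filter, 7 of 64 changed by 1.5-fold, 46 of 64 changed by 2-fold and 63 of 64 changed by 4-fold were recovered, with 8 unchanged genes among 124 called of 15024 tested. A simulated list of 20 raised genes was called, and 0 of 100 lists of unchanged genes were called by camera. The simulated genes were drawn independently of each other. Estimated correlations in the real lists were high for some, such as 0.65 for CUB-like genes and 0.92 for oocyte and eggshell genes. The simulation thus cannot show how often camera calls unchanged lists of correlated genes. Of 300 simulated genes that followed a score like the adult-stage score, 75 were called without and 0 with the score as a covariate. The covariate was the very score built into these genes, so this outcome was fixed in advance. It cannot show that such a fit parts stage from bacterium. How many changed genes are recovered with the covariate was not simulated.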

Results

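Gene expression was measured by RNA sequencing in whole C. elegans of the wild-type strain N2. Mid-L4 larvae, the last larval stage, were kept for 12 h at 25 °C on lawns of the pathogen Pseudomonas aeruginosa PA01 or of Escherichia coli OP50, the usual laboratory food. Each group has 4 libraries, and the labels do not say whether the replicates came from separate worm cultures. The p-values thus measure only the spread between these libraries, which can be technical. The comparison asks which transcripts differ between animals on the pathogen and animals on the food bacterium. The OP50 libraries hold 18546196, 16052703, 16213416 and 29210505 reads over genes. The PA01 libraries hold 20308975, 15864845, 15262523 and 32243426 reads. At the lowest depth 1 read on a gene of 1 kb is worth 0.0655 RPKM (reads per kilobase, scaled to the depth of the library). Levels are means ± SD in RPKM over 4 libraries per group, and a level that rose or fell is given from OP50 to PA01. Fold changes are on the log2(RPKM + 1) scale, which understates the change of low genes.

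The libraries separated by bacterium on the leading principal component, which held 53.5% of the variance. Across genes, which are not independent replicates, Pearson's r was 0.931 to 0.982 among OP50 libraries and 0.919 to 0.981 among PA01 libraries. Between the groups r was 0.839 to 0.952. The libraries also differed in markers of adulthood. An adult-stage score was computed as the mean log2 value of 44 tested yolk, oocyte, eggshell and adult cuticle genes, centred over the 8 libraries. It was -0.62, -0.55, -1.23 and -2.25 in OP50 replicates 1 to 4 and 2.0, 1.43, 0.90 and 0.33 in PA01 replicates 1 to 4. The group means were -1.16 ± 0.79 on OP50 and 1.16 ± 0.71 on PA01 (SD, n = 4; difference 2.33, exact permutation test, two-sided p = 0.0286, the smallest that 70 assignments allow). The score was defined after the data were seen, from lists fixed before the data were examined. Of its 44 genes 28 are oocyte and eggshell genes. The mean of the adult cuticle genes alone did not separate the groups, at 8.81 in OP50 replicate 1 and 8.47 in PA01 replicate 1. It was 9.73 to 9.94 in PA01 replicates 2 to 4 and 6.13 to 8.47 in OP50 replicates 2 to 4.

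**Figure D1:**
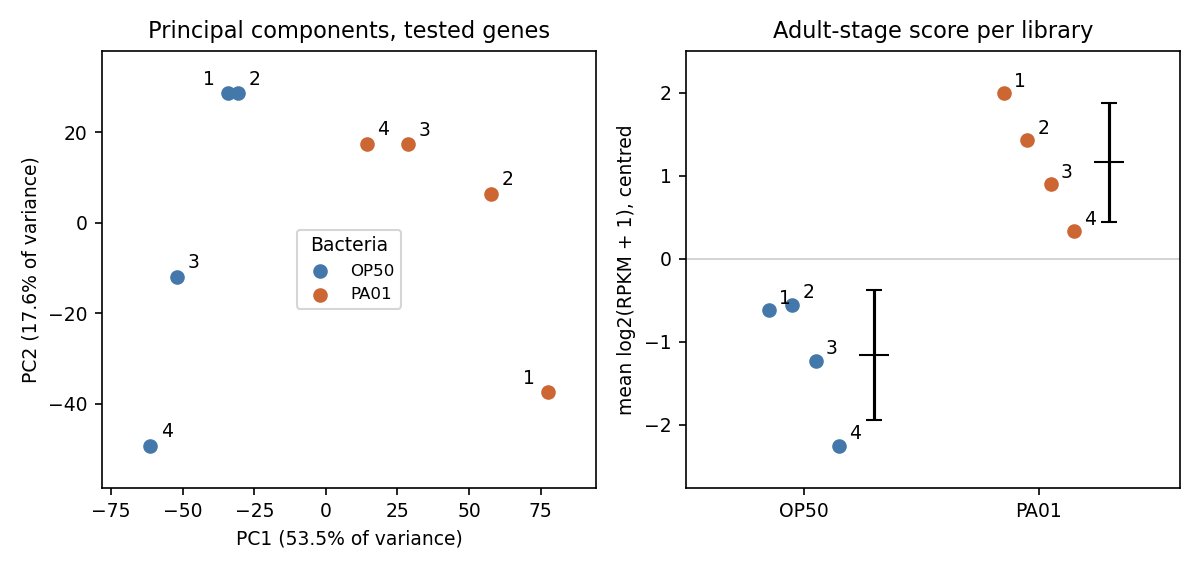
Left, the 8 libraries on the leading principal components of the log2(RPKM + 1) values of the tested genes, with replicate numbers. Right, the adult-stage score per library (mean log2(RPKM + 1) of 44 genes, centred) with group mean and SD in black; the highest OP50 library is at -0.55 and the lowest PA01 library at 0.33.

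Called higher on PA01 were all tested oocyte and eggshell genes, many sperm genes and most tested genes of a secreted CUB-like family known from immunity to intestinal pathogens. Some cuticle collagen and yolk genes were called higher as well. Called lower were some genes of the propionate shunt, the methionine cycle, the TCA cycle and the mitochondrial genome, and some UDP-glucuronosyltransferases, lysozymes and cathepsins. The strongest fall was in an arginine kinase gene, argk-1 (chromosome V, 16103935 to 16105899 of build WBcel235). Its level fell from 618 ± 88.1 to 0.477 ± 0.486 RPKM (log2 fold change -8.75, adjusted p = 8.09e-07). The strongest rise was in the cuticle collagen gene col-81 (chromosome II, 11012494 to 11013760). There the level rose from 31.3 ± 29.1 to 3009.8 ± 1947 RPKM (log2 fold change 6.95, adjusted p = 0.00547). Of 14885 genes tested with limma, 2046 (13.7%) were called at the adjusted threshold, 1385 higher and 661 lower on PA01. Of these, 741 rose and 284 fell by 2-fold or more. In 2006 of the called genes all PA01 values lay on one side of all OP50 values. Over all tested genes 25.6% were so separated, where chance gives 2.86%. Among called genes 67.7% were higher, against 53.0% after median-ratio scaling and 42.3% after quantile normalization, which moves the fold changes of all tested genes by a median of -0.13.

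The number of called genes depended on single libraries. It fell to 992 without OP50 replicate 1 (631 higher, 361 lower) and to 619 without OP50 replicate 3 (395 and 224). It was 744 without PA01 replicate 2 (473 and 271) and 1052 without PA01 replicate 3 (667 and 385), and without OP50 replicate 2 the lower genes numbered 360. The counts at 2-fold or more fell to 325 higher and 155 lower without OP50 replicate 3 and to 385 and 166 without PA01 replicate 2. When every gene with a read was tested, 27593 listed genes being the pool, 1101 were called (747 higher, 354 lower). A fit with the adult-stage score as a covariate, added after the data were seen, called 116 genes (89 higher, 27 lower). Of these 88 were among the 2046 and kept their direction.

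**Figure D2:**
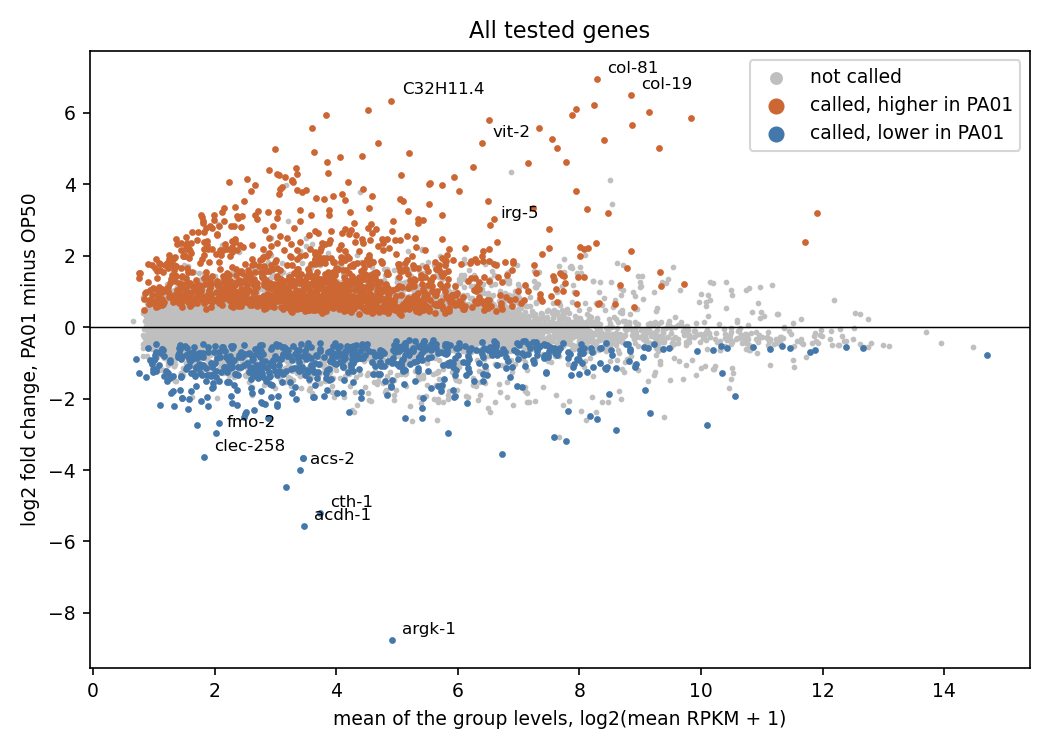
Each point is 1 of the 14885 tested genes: mean of the group levels (log2 of mean RPKM + 1) against log2 fold change, PA01 minus OP50. Orange points are the 1385 called genes that were higher on PA01, blue points the 661 that were lower; argk-1 lies lowest at -8.75 and col-81 highest at 6.95.

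Among the 8 largest rises by the rule fixed beforehand, 6 were cuticle collagens. Besides col-81 these were the adult collagen col-19 (log2 fold change 6.48, adjusted p = 0.00949), col-139 (6.21, adjusted p = 0.00317), col-140 (6.10, adjusted p = 0.00350), col-129 (6.02, adjusted p = 0.00576) and col-62 (5.94, adjusted p = 0.000737). The CUB-like gene C32H11.4 lies on chromosome IV, 12921320 to 12923210. Its mRNA rose from 2.21 ± 0.811 to 279 ± 138.5 RPKM (log2 fold change 6.34, adjusted p = 0.000129). The piRNA locus 21ur-12304 rose by 6.09 (adjusted p = 0.00217). It lies inside the collagen gene col-137, and the libraries' strand is not stated, so its reads can come from that gene.

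The 8 largest falls were argk-1, acdh-1 (-5.57, adjusted p = 0.000978), cth-1 (-5.21, adjusted p = 2.74e-05), F21C10.9 (-4.47, adjusted p = 1.37e-05), acs-2 (-4.01, adjusted p = 0.00140), the overlapping piRNA loci 21ur-11193 and 21ur-9519, and clec-258. Both piRNA loci fell by 3.66 (adjusted p = 0.0162), and their calls were lost without OP50 replicate 3 (adjusted p = 0.0552). The C-type lectin clec-258 was at 0 reads in all PA01 libraries against 11.52 ± 1.97 RPKM on OP50. That is at least 37.7-fold lower if 3 reads are set as the floor in each PA01 library (0.305 RPKM). Here acdh-1 is an acyl-CoA dehydrogenase of the propionate shunt, cth-1 a cystathionine gamma-lyase and acs-2 an acyl-CoA synthetase of fatty acid breakdown. In the fit with the adult-stage score, argk-1, cth-1, F21C10.9, clec-258, C32H11.4 and col-140 stayed called. The other genes among these rises and falls that are not part of the score lost the call. Their log2 fold changes were then -4.64 for acdh-1, -2.68 for acs-2, -3.28 for 21ur-11193 and 21ur-9519 and 4.63 for 21ur-12304. For col-81, col-129 and col-139 they were 2.45, 1.98 and 2.56. The median SE over all genes grew from 0.198 to 0.341 in that fit, so lost precision can be a part of the lost calls.

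Secreted immune proteins of the intestine formed the clearest immune group. Of 18 tested CUB-like genes 13 rose and none fell (14 rose adjusted over the list alone; median log2 fold change 1.95, camera adjusted p = 1.33e-10, or 0.512 with an estimated correlation). Levels of dod-24 rose from 64.2 ± 10.8 to 935 ± 236 RPKM (log2 fold change 3.82, adjusted p = 7.50e-05). The neighbouring C32H11.9 rose from 10.5 ± 4.71 to 186 ± 57.7 RPKM (log2 fold change 4.04, adjusted p = 0.000885). Expression of F55G11.2 rose from 1.87 ± 0.492 to 39.6 ± 12 RPKM (log2 fold change 3.78, adjusted p = 0.000206). Of 12 effectors of the p38 MAP kinase pathway 6 rose and none fell (8 rose adjusted over the list alone; median log2 fold change 0.96, camera adjusted p = 1.78e-05, or 0.512 with an estimated correlation). Among them irg-5 rose from 32.9 ± 11 to 254 ± 114.4 RPKM (log2 fold change 2.87, adjusted p = 0.00581). The C-type lectin clec-85 rose from 22 ± 5.82 to 124 ± 17.9 RPKM (log2 fold change 2.47, adjusted p = 0.000391). Most of the 12 effectors, irg-5 and dod-24 among them, are also members of the CUB-like list, so these lists are not independent. The 12 components of the p38 pathway itself held 0 genes called by limma, 2 at an unadjusted p under 0.05 and 1 called with limma voom. None passed adjusted over the list alone, and the list was not called (camera adjusted p = 0.575, median 0.01, mean -0.02). In the fit with the adult-stage score, which was higher on PA01 by 2.33, 12 CUB-like genes and 6 p38 effectors were called.

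Of 7 tested genes of the ZIP-2 surveillance response 2 rose and none fell (2 rose adjusted over the list alone). The list was not called by camera (adjusted p = 0.223) and was called by fry (adjusted p = 0.00639). In this list irg-3 rose from 5.75 ± 1.42 to 199.7 ± 51.2 RPKM (log2 fold change 4.88, adjusted p = 2.53e-05). Its other called gene irg-7 rose from 69.6 ± 12 to 117 ± 16.7 RPKM (log2 fold change 0.75, adjusted p = 0.0217). The call of irg-7 was lost without OP50 replicate 1, 2 or 3 or PA01 replicate 2 or 3 (adjusted p up to 0.0576). The marker irg-1, at 13 ± 5.13 RPKM on OP50 and 14.7 ± 5.85 RPKM on PA01, was not called (log2 fold change 0.17, adjusted p = 0.773). The p38 effector gene irg-4, at 21 ± 8.42 RPKM on OP50 and 34.7 ± 20.6 RPKM on PA01, was not called (log2 fold change 0.56, adjusted p = 0.434). The p38 reporter gene T24B8.5, at 2.43 ± 0.795 RPKM on OP50 and 5.17 ± 1.58 RPKM on PA01, was not called (log2 fold change 0.84, adjusted p = 0.0570). It was called when protein-coding genes alone were tested.

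Of 24 tested genes of the intracellular pathogen response 2 fell and none rose (2 fell adjusted over the list alone; median log2 fold change -0.17, camera adjusted p = 0.0287, or 0.512 with an estimated correlation). The list call was lost without OP50 replicate 4 (camera adjusted p = 0.0675) or PA01 replicate 4 (camera adjusted p = 0.104). Among the called genes was skr-4 (log2 fold change -0.61, adjusted p = 0.0166). The call of skr-4 was lost without PA01 replicate 2 (adjusted p up to 0.0535). The marker pals-5 was below the filter, at 0.254 ± 0.202 RPKM on OP50 and 0.0521 ± 0.0348 RPKM on PA01. C-type lectins went both ways. Of 91 tested genes 19 rose and 10 fell (22 rose and 11 fell adjusted over the list alone; camera adjusted p = 0.232). Rises were led by clec-174 (log2 fold change 4.40, adjusted p = 2.19e-05) and clec-3 (log2 fold change 4.05, adjusted p = 0.000396). The marker clec-60, at 3.35 ± 1.14 RPKM on OP50 and 4.96 ± 0.941 RPKM on PA01, was not called (log2 fold change 0.48, adjusted p = 0.151).

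Some lysozymes and caenopores, which are antibacterial enzymes and pore-forming proteins of the gut, were called lower. Of 7 tested lysozymes 3 fell and none rose (1 rose and 3 fell adjusted over the list alone; median log2 fold change -0.17, camera adjusted p = 0.0273, or 0.512 with an estimated correlation). Levels of lys-4 fell from 83.2 ± 27.1 to 13.6 ± 4.62 RPKM (log2 fold change -2.54, adjusted p = 0.00229). The invertebrate-type lysozyme ilys-5 fell from 493 ± 45.2 to 100.5 ± 32.4 RPKM (log2 fold change -2.34, adjusted p = 0.00149). The marker lys-7 fell from 110.3 ± 23.6 to 46 ± 13.4 RPKM (log2 fold change -1.27, adjusted p = 0.0165). The call of lys-7 was lost without OP50 replicate 3 (adjusted p up to 0.0525). The list call of lysozymes was lost under quantile normalization (camera adjusted p = 0.0656), with the replicate number as a block (0.0877) and without OP50 replicate 4 (0.0529). Of 19 caenopores 4 fell and none rose (1 rose and 4 fell adjusted over the list alone; camera adjusted p = 0.111). The largest fall was in spp-17, which fell from 2897 ± 792 to 418 ± 65.8 RPKM (log2 fold change -2.75, adjusted p = 0.000724). Likewise spp-4 fell from 89.4 ± 14.2 to 32 ± 5.36 RPKM (log2 fold change -1.46, adjusted p = 0.00220).

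Of 37 antimicrobial peptide genes 1 rose and 3 fell (1 fell adjusted over the list alone; median log2 fold change -0.24, camera adjusted p = 0.0108, or 0.539 with an estimated correlation). The largest fall was in fipr-21 (log2 fold change -1.27, adjusted p = 0.00878). The list call was lost under quantile normalization (camera adjusted p = 0.0716), with every gene above 0 tested (0.0894) and without PA01 replicate 3 (0.0608). Without OP50 replicate 4 the list had a camera adjusted p = 0.146 and a median log2 fold change of 0.065. Of 23 cathepsin-type proteases 2 rose and 7 fell (3 rose and 8 fell adjusted over the list alone; median log2 fold change -0.16, camera adjusted p = 0.00124, or 0.512 with an estimated correlation). The cathepsin B gene cpr-5 fell from 655 ± 56 to 73.2 ± 22.2 RPKM (log2 fold change -3.19, adjusted p = 0.000211). Its paralog cpr-1 fell from 1029 ± 67.5 to 145 ± 52.5 RPKM (log2 fold change -2.88, adjusted p = 0.000623). The aspartyl protease asp-14 rose from 218 ± 46 to 963 ± 218 RPKM (log2 fold change 2.13, adjusted p = 0.00185). Given the adult-stage score as covariate, 1 lysozyme, 1 caenopore and 3 cathepsins were called lower. The medians were then 0.24, 0.08 and 0.16 for lysozymes, caenopores and antimicrobial peptides and 0.00 for cathepsins, so the first 3 had turned.

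**Figure D3:**
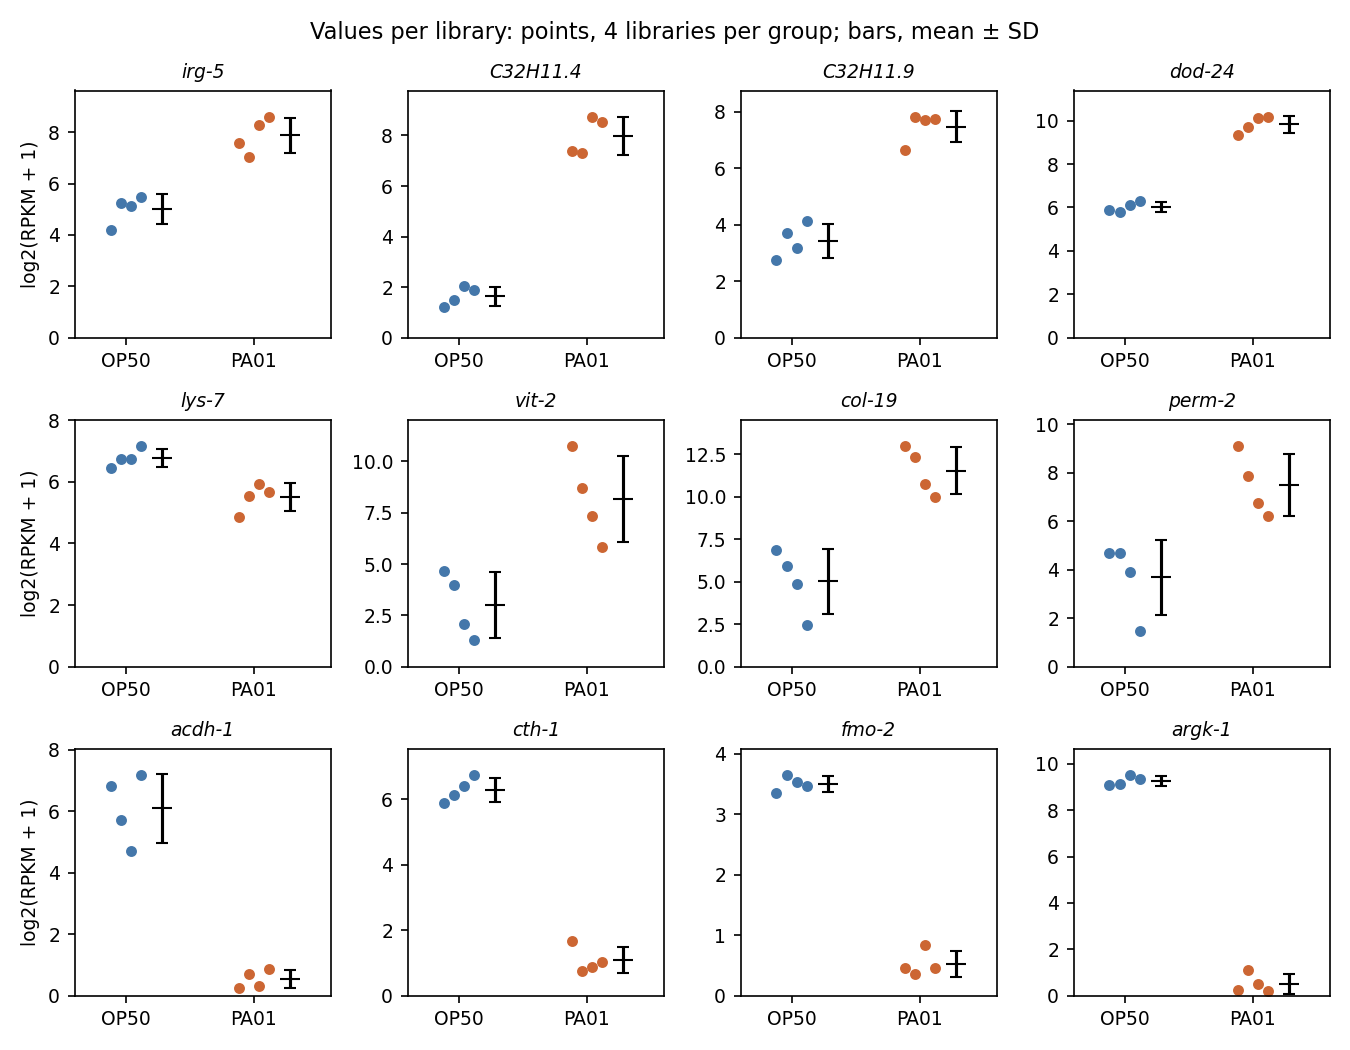
log2(RPKM + 1) per library for 12 genes named in the text: colored points are the 4 libraries of each group, black bars the mean ± SD. All PA01 values of irg-5, C32H11.4, C32H11.9, dod-24, vit-2, col-19 and perm-2 lie above, and all of lys-7, acdh-1, cth-1, fmo-2 and argk-1 below, the OP50 values.

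Genes of oocytes and sperm were called higher on PA01, as was the adult-stage score (by 2.33). All 28 tested oocyte and eggshell genes rose (28 adjusted over the list alone; median log2 fold change 2.33, camera adjusted p = 4.80e-14, or 0.512 with an estimated correlation). The permeability barrier gene perm-4 rose from 8.53 ± 5.24 to 113 ± 86.6 RPKM (log2 fold change 3.58, adjusted p = 0.0137). The related marker perm-2 rose from 16 ± 11 to 241 ± 216 RPKM (log2 fold change 3.8, adjusted p = 0.0267). The call of perm-2 was lost without OP50 replicate 3 or PA01 replicate 1 or 2 (adjusted p up to 0.0751). The eggshell proteoglycan gene cpg-3 rose from 5.04 ± 3.28 to 57.1 ± 39.5 RPKM (log2 fold change 3.22, adjusted p = 0.0135). The oocyte RNA-binding protein gene puf-5 rose from 2.88 ± 1.43 to 36.3 ± 24.1 RPKM (log2 fold change 3.13, adjusted p = 0.010). Of 89 tested sperm genes 39 rose and none fell (65 rose and 1 fell adjusted over the list alone; median log2 fold change 1.42, camera adjusted p = 1.41e-12, or 0.512 with an estimated correlation). The major sperm protein gene msp-10 rose from 44.1 ± 23.2 to 221 ± 85.2 RPKM (log2 fold change 2.39, adjusted p = 0.0133). Levels of nspd-10 rose from 7.70 ± 2.76 to 44.4 ± 15.3 RPKM (log2 fold change 2.39, adjusted p = 0.00344). The msp genes are near-identical copies, so reads can be shared among them.

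Of 27 DNA replication and cell cycle genes 14 rose and none fell (23 rose adjusted over the list alone; median log2 fold change 0.80, camera adjusted p = 8.85e-09, or 0.512 with an estimated correlation). The B-type cyclins cyb-2.2 (log2 fold change 2.09, adjusted p = 0.00659) and cyb-2.1 (log2 fold change 1.95, adjusted p = 0.0118) rose most. Of 23 general germ cell markers 8 rose and none fell (9 rose adjusted over the list alone; median log2 fold change 0.28, camera adjusted p = 0.00499, or 0.578 with an estimated correlation). These include mex-1 (log2 fold change 2.45, adjusted p = 0.0158) and gld-1 (log2 fold change 1.00, adjusted p = 0.0349). The call of gld-1 was lost without OP50 replicate 1 or 3 or PA01 replicate 1, 2 or 3 (adjusted p up to 0.0909). The list of germ cell markers lost its call without OP50 replicate 4 (camera adjusted p = 0.0529). With the score as covariate limma called 0 sperm, germ cell or replication genes of these lists (6, 5 and 3 at an unadjusted p under 0.05). The medians were then -0.12, -0.19 and 0.045. With a score from yolk and cuticle genes alone limma called 0 of the 28 oocyte and eggshell genes (6 at an unadjusted p under 0.05), with a median of 0.97 (median SE 0.51).

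Some yolk and adult cuticle genes, from lists that the score itself contains, were called higher too. Of 6 vitellogenins 2 rose and none fell (3 rose adjusted over the list alone; median log2 fold change 2.96, camera adjusted p = 0.0188, or 0.539 with an estimated correlation). Levels of vit-2 rose from 11 ± 11 to 591 ± 773 RPKM (log2 fold change 5.15, adjusted p = 0.0240). Levels of vit-6 rose from 30.6 ± 26.9 to 1235 ± 1422 RPKM (log2 fold change 5.01, adjusted p = 0.0209). The call of vit-2 was lost without OP50 replicate 3 or PA01 replicate 2 (adjusted p up to 0.0758). The call of vit-6 was lost without OP50 replicate 3 or PA01 replicate 2 (adjusted p up to 0.0678). The list call was lost without OP50 replicate 4 (camera adjusted p = 0.0576). Of 146 tested collagens 27 rose and 3 fell (31 rose and 5 fell adjusted over the list alone; camera adjusted p = 0.174). Of 10 adult cuticle collagens 3 rose and none fell (3 rose adjusted over the list alone; camera adjusted p = 0.180). These are col-19, col-62 and col-7 (log2 fold change 5.57, adjusted p = 0.00175). Of 25 tested moulting cycle genes limma called 0 (13 at an unadjusted p under 0.05, 1 called with limma voom, 0 adjusted over the list alone). Still, camera called the list lower (median log2 fold change -1.01, camera adjusted p = 0.000334, or 0.539 with an estimated correlation). The moulting gene qua-1, at 615 ± 376 RPKM on OP50 and 297 ± 195 RPKM on PA01, was not called (log2 fold change -1.25, adjusted p = 0.287). Likewise mlt-10, at 462 ± 219 RPKM on OP50 and 283 ± 176 RPKM on PA01, was not called (log2 fold change -0.96, adjusted p = 0.363). With the score as covariate 4 collagens were called higher and the median of the moulting genes was -0.0050 (median SE 1.16). With a score that leaves out the vitellogenins limma called 0 of these 6 (0 at an unadjusted p under 0.05), and their median turned to -2.04 (median SE 1.84). With a score that leaves out the adult cuticle collagens limma called 1 of these 10 (3 at an unadjusted p under 0.05), with a median of 0.75 (median SE 1.57).

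The propionate shunt breaks down propionate without vitamin B12. Of 7 tested genes of this propionate shunt 3 fell and none rose (5 fell adjusted over the list alone; median log2 fold change -0.58, camera adjusted p = 4.14e-05, or 0.512 with an estimated correlation). The reporter gene of vitamin B12 status, acdh-1, lies on chromosome I, 6497453 to 6499464. It fell from 82.9 ± 54.4 to 0.466 ± 0.301 RPKM (log2 fold change -5.57, adjusted p = 0.000978). The dehydrogenase gene hphd-1 fell from 32.2 ± 10.6 to 10.3 ± 2.87 RPKM (log2 fold change -1.55, adjusted p = 0.0107). Levels of ech-6 fell from 375 ± 91.1 to 183 ± 12 RPKM (log2 fold change -1.01, adjusted p = 0.0119). Of 19 genes of the methionine and S-adenosylmethionine cycle and related propionate breakdown 1 rose and 8 fell (1 rose and 8 fell adjusted over the list alone; median log2 fold change -0.40, camera adjusted p = 0.000321, or 0.512 with an estimated correlation). The largest fall was in cth-1 (chromosome V, 16100698 to 16102651). It fell from 79.6 ± 20.7 to 1.19 ± 0.672 RPKM (log2 fold change -5.21, adjusted p = 2.74e-05). The S-adenosylmethionine synthetase gene sams-1 fell from 184 ± 42.4 to 71.9 ± 24.1 RPKM (log2 fold change -1.39, adjusted p = 0.0179). The nuclear receptor gene nhr-114, which acts in this cycle, fell from 21.7 ± 3.82 to 10.1 ± 2.16 RPKM (log2 fold change -1.04, adjusted p = 0.0142). The call of sams-1 was lost without OP50 replicate 3 (adjusted p up to 0.0573). The call of nhr-114 was lost without OP50 replicate 3 (adjusted p up to 0.0502). In the fit with the adult-stage score cth-1 was called and the other genes of both lists were not. The medians were then -0.18 for the shunt and -0.014 for the methionine cycle.

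Several lists of energy metabolism were called lower. Of 23 TCA and glyoxylate cycle genes 8 fell and none rose (14 fell adjusted over the list alone; median log2 fold change -0.47, camera adjusted p = 3.15e-08, or 0.512 with an estimated correlation). These include citrate synthase, cts-1 (log2 fold change -0.75, adjusted p = 0.0248), and idhb-1 (log2 fold change -0.61, adjusted p = 0.0174). Of 31 nuclear genes of the electron transport chain and ATP synthase 6 fell and none rose (1 rose and 15 fell adjusted over the list alone; median log2 fold change -0.44, camera adjusted p = 5.34e-07, or 0.512 with an estimated correlation). Examples are sdha-1 (log2 fold change -0.77, adjusted p = 0.0281) and gas-1 (log2 fold change -0.71, adjusted p = 0.0184). Of 12 protein-coding genes of the mitochondrial genome 5 fell and none rose (8 fell adjusted over the list alone; median log2 fold change -0.64, camera adjusted p = 5.96e-05, or 0.512 with an estimated correlation). There ND1 fell from 701 ± 36.9 to 395 ± 66.3 RPKM (log2 fold change -0.84, adjusted p = 0.0128). Of 24 genes of glycolysis and gluconeogenesis 3 rose and 8 fell (4 rose and 11 fell adjusted over the list alone; median log2 fold change -0.36, camera adjusted p = 0.00106, or 0.512 with an estimated correlation). Rises were seen in gpd-1 (log2 fold change 1.79, adjusted p = 0.00717) and the hexokinase hxk-1 (log2 fold change 1.22, adjusted p = 0.0154), and a fall in the gluconeogenic pck-1 (log2 fold change -1.11, adjusted p = 0.0204). The call of cts-1 was lost without OP50 replicate 1 or 3 or PA01 replicate 2 (adjusted p up to 0.0643). The call of idhb-1 was lost without OP50 replicate 3 (adjusted p up to 0.0567). The call of sdha-1 was lost without OP50 replicate 1, 3 or 4 or PA01 replicate 2 (adjusted p up to 0.0802). The call of gas-1 was lost without OP50 replicate 3 (adjusted p up to 0.0591). The call of hxk-1 was lost without OP50 replicate 3 (adjusted p up to 0.0522). The call of pck-1 was lost without OP50 replicate 3 or PA01 replicate 2 (adjusted p up to 0.0614). In the fit with the adult-stage score limma called 0 genes of these 4 lists (1, 1, 5 and 3 at an unadjusted p under 0.05). Their medians were then -0.34, -0.06, -0.81 and -0.22 for the TCA, electron transport, mitochondrial genome and glycolysis lists.

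Fat metabolism showed no single direction. Of 41 tested genes of fatty acid breakdown and fasting 6 rose and 6 fell (10 rose and 10 fell adjusted over the list alone; camera adjusted p = 0.418). Levels of acs-2 fell from 39.6 ± 10.5 to 1.76 ± 1.5 RPKM (log2 fold change -4.01, adjusted p = 0.00140). The carnitine palmitoyltransferase gene cpt-4 rose from 2.49 ± 0.472 to 14.2 ± 6.36 RPKM (log2 fold change 1.98, adjusted p = 0.0165). The call of cpt-4 was lost without OP50 replicate 3 or PA01 replicate 2 (adjusted p up to 0.0533). This list has a median log2 fold change of 0.03 and a mean of -0.15, and the set test points lower. Of 24 genes of fatty acid synthesis and desaturation 1 rose and 3 fell (2 rose and 8 fell adjusted over the list alone; median log2 fold change -0.47, camera adjusted p = 0.000858, or 0.512 with an estimated correlation). These include let-767 (log2 fold change -0.82, adjusted p = 0.0152). The call of let-767 was lost without OP50 replicate 3 (adjusted p up to 0.0508). Of 12 tested genes of iron and haem handling 2 fell and none rose (5 fell adjusted over the list alone; median log2 fold change -0.53, camera adjusted p = 0.00720, or 0.512 with an estimated correlation). The list lost its call with a filter at a mean of 5 RPKM (camera adjusted p = 0.0963). The largest fall was in hrg-7 (log2 fold change -2.39, adjusted p = 0.000692). The ferritin marker ftn-1, at 6.0 ± 2.97 RPKM on OP50 and 3.65 ± 1.44 RPKM on PA01, was not called (log2 fold change -0.53, adjusted p = 0.391). Of these 3 lists limma called 0 genes with the adult-stage score as covariate (8, 2 and 3 at an unadjusted p under 0.05). Their medians were then 0.06, -0.04 and -0.07.

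Members of 3 detoxification families were called lower more often than higher. Of 45 tested UDP-glucuronosyltransferases 2 rose and 18 fell (3 rose and 23 fell adjusted over the list alone; median log2 fold change -0.55, camera adjusted p = 9.40e-09, or 0.512 with an estimated correlation). Levels of ugt-65 fell from 23.3 ± 4.30 to 7.99 ± 3.01 RPKM (log2 fold change -1.49, adjusted p = 0.0141). The gene ugt-19 fell from 9.71 ± 1.52 to 3.41 ± 0.748 RPKM (log2 fold change -1.28, adjusted p = 0.00566). In contrast ugt-18 rose from 2.47 ± 0.456 to 15.8 ± 3.46 RPKM (log2 fold change 2.26, adjusted p = 0.000504). Of 45 cytochrome P450 genes 5 rose and 11 fell (5 rose and 12 fell adjusted over the list alone; median log2 fold change -0.38, camera adjusted p = 4.14e-05, or 0.512 with an estimated correlation). The gene cyp-35C1 fell from 10 ± 1.05 to 1.42 ± 0.244 RPKM (log2 fold change -2.19, adjusted p = 0.000200). Likewise cyp-35A2 fell from 9.43 ± 4.13 to 1.27 ± 0.327 RPKM (log2 fold change -2.13, adjusted p = 0.00344). Of 12 P-glycoprotein pumps 4 fell and none rose (7 fell adjusted over the list alone; median log2 fold change -0.45, camera adjusted p = 6.04e-05, or 0.512 with an estimated correlation). These include pgp-1 (log2 fold change -0.75, adjusted p = 0.0417). The call of pgp-1 was lost without any 1 of the 8 libraries (adjusted p up to 0.0943).

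Glutathione S-transferases went both ways. Of 34 tested 6 rose and 5 fell (9 rose and 6 fell adjusted over the list alone; camera adjusted p = 0.946, median log2 fold change -0.01, mean 0.18). Levels of gst-38 rose from 46.1 ± 8.30 to 484 ± 146 RPKM (log2 fold change 3.33, adjusted p = 0.000245). Levels of gst-7 rose from 90.6 ± 13 to 263 ± 51.3 RPKM (log2 fold change 1.52, adjusted p = 0.00239). Both belong to the SKN-1 oxidative stress list. Of 13 tested genes of this list 3 rose and none fell (5 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0706). The SKN-1 reporter gene gst-4, at 19.3 ± 2.91 RPKM on OP50 and 22.9 ± 8.54 RPKM on PA01, was not called (log2 fold change 0.17, adjusted p = 0.698). After the adult-stage score was added, 3 glutathione S-transferases were called higher and 2 cytochrome P450 genes lower. That fit called 0 UDP-glucuronosyltransferases (9 at an unadjusted p under 0.05), with a median of -0.04 for that list. The medians of the cytochrome P450 and P-glycoprotein lists were then -0.11 and -0.08.

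None of 3 stress reporters was called. Of 17 cytosolic heat shock genes, 33 proteasome subunits, 22 genes of the endoplasmic reticulum stress response and 11 genes of osmotic stress limma and limma voom each called 0 (2, 1, 3 and 3 at an unadjusted p under 0.05). None passed in any of these lists adjusted over the list alone. The proteasome list has a median of -0.0084 and a mean of 0.011, and the set test points lower. Camera gave the lists an adjusted p = 0.341, 0.631, 0.0422 and 0.175. The list of the endoplasmic reticulum was thus called lower, with a median log2 fold change of -0.14 (camera adjusted p = 0.539 with an estimated correlation). Its call was lost under quantile normalization (camera adjusted p = 0.12) and without OP50 replicate 1 (0.0609), OP50 replicate 3 (0.0922) or PA01 replicate 1 (0.0885). The reporter hsp-16.2, at 5.76 ± 5.45 RPKM on OP50 and 3.65 ± 2.36 RPKM on PA01, was not called (log2 fold change -0.32, adjusted p = 0.761). The reporter hsp-4, at 208 ± 25.8 RPKM on OP50 and 242 ± 9.19 RPKM on PA01, was not called (log2 fold change 0.23, adjusted p = 0.232). The reporter hsp-6, at 229 ± 24.7 RPKM on OP50 and 189 ± 15.8 RPKM on PA01, was not called (log2 fold change -0.27, adjusted p = 0.172). Of 17 genes of the mitochondrial stress response 2 fell and none rose (1 rose and 4 fell adjusted over the list alone; median log2 fold change -0.23, camera adjusted p = 0.00920, or 0.512 with an estimated correlation). The protease gene spg-7 fell from 109 ± 9.93 to 70.8 ± 3.08 RPKM (log2 fold change -0.61, adjusted p = 0.0136).

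Of 17 hypoxia, hydrogen sulphide and cyanide genes 1 rose and 3 fell (1 rose and 5 fell adjusted over the list alone; median log2 fold change -0.50, camera adjusted p = 0.00172, or 0.539 with an estimated correlation). The flavin monooxygenase gene fmo-2 fell from 10.3 ± 0.975 to 0.451 ± 0.226 RPKM (log2 fold change -2.97, adjusted p = 4.46e-05). The hypoxia factor gene hif-1 itself fell from 179 ± 19.9 to 117 ± 7.48 RPKM (log2 fold change -0.60, adjusted p = 0.0179). The call of hif-1 was lost without OP50 replicate 3 (adjusted p up to 0.0517). The cyanide marker cysl-2, at 175 ± 45 RPKM on OP50 and 80 ± 39.4 RPKM on PA01, was not called (log2 fold change -1.26, adjusted p = 0.0762). The gene nhr-57, at 8.63 ± 1.78 RPKM on OP50 and 5.18 ± 1.15 RPKM on PA01, was not called (log2 fold change -0.64, adjusted p = 0.0609). It was called after median-ratio scaling (adjusted p = 0.0424) and quantile normalization (0.0266). Of 15 DAF-16 FOXO targets 1 rose and 3 fell (1 rose and 5 fell adjusted over the list alone; camera adjusted p = 0.376). Their median was 0.27 and their mean 0.07, and the set test pointed lower. The marker sod-3, at 11 ± 4.74 RPKM on OP50 and 4.80 ± 0.779 RPKM on PA01, was not called (log2 fold change -0.96, adjusted p = 0.0765). The gene sod-3 was called after quantile normalization (adjusted p = 0.0467) and without OP50 replicate 1 (0.0176). Of 23 autophagy genes 3 rose and none fell (3 rose adjusted over the list alone; camera adjusted p = 0.389). Once the adult-stage score was a covariate, fmo-2 was the 1 called gene of the hypoxia list, whose median turned to 0.17. The medians of the endoplasmic reticulum and mitochondrial stress lists were then 0.13 and -0.15.

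Markers of muscle, neurons, intestine and epidermis were tested as lists. Of 21 muscle markers 3 fell and none rose (3 fell adjusted over the list alone; median log2 fold change -0.34, camera adjusted p = 4.32e-06, or 0.512 with an estimated correlation). These include hlh-1 (log2 fold change -0.95, adjusted p = 0.0190). The call of hlh-1 was lost without OP50 replicate 3 (adjusted p up to 0.0634). Of 22 neuronal markers 2 fell and none rose (2 fell adjusted over the list alone; median log2 fold change -0.16, camera adjusted p = 0.0108, or 0.613 with an estimated correlation). The list lost its call without OP50 replicate 4 (camera adjusted p = 0.0546). A called member was mec-12 (log2 fold change -0.63, adjusted p = 0.0274). The call of mec-12 was lost without OP50 replicate 1 or 3 or PA01 replicate 2 (adjusted p up to 0.0817). Of 18 intestinal markers 2 fell and none rose (2 fell adjusted over the list alone; camera adjusted p = 0.317). Their median was 0.02 and their mean -0.02. The gut esterase gene ges-1 fell from 53.5 ± 6.96 to 26.7 ± 3.11 RPKM (log2 fold change -0.97, adjusted p = 0.00610).

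Of 17 epidermal markers limma and limma voom called 0 (6 at an unadjusted p under 0.05, 0 adjusted over the list alone; median log2 fold change -0.41, camera adjusted p = 0.00259, or 0.512 with an estimated correlation). The ribosomal protein list holds the small-subunit, acidic and ubiquitin-fusion genes and the rpl-41 genes, without the other rpl genes. Its median log2 fold change was -0.35 (camera adjusted p = 4.70e-07, or 0.512 with an estimated correlation). Of its 37 genes 3 fell (0 adjusted over the list alone). Among them were rps-14 (log2 fold change -0.70, adjusted p = 0.0383) and rps-24 (log2 fold change -0.58, adjusted p = 0.0325), whose calls were lost under quantile normalization. The call of rps-14 was lost without OP50 replicate 1, 2 or 3 or PA01 replicate 1, 2, 3 or 4 (adjusted p up to 0.10). The call of rps-24 was lost without OP50 replicate 1, 2 or 3 or PA01 replicate 1, 2, 3 or 4 (adjusted p up to 0.0865). Of the muscle, neuronal, intestinal, epidermal and ribosomal lists limma called 0 genes with the adult-stage score as covariate (2, 3, 5, 1 and 10 at an unadjusted p under 0.05). Their medians were then -0.24, 0.32, 0.57, 0.13 and 0.28.

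Across the 55 lists fixed beforehand camera called 33, 7 higher and 26 lower, with a preset correlation of 0.01. With an estimated correlation it called 0 (1 list at an unadjusted p under 0.05). Fry, which asks whether the genes of a list move together, called 17, of which 16 are among the 33. In other splits of the 8 libraries camera called up to 30 lists, against 33 in the real one, so a list call at the preset correlation says little by itself.

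Gene classes, named by the letters of the gene symbol, were tested among genes changed by 2-fold or more with Fisher's exact test, 151 classes in both directions. Of these 302 tests 13 passed, in 12 classes, as clec passed in both directions. Fisher's test takes the genes as independent, which members of a family that vary together or share reads are not. The class p-values can thus be too small, as for the msp genes, whose sperm list had an estimated correlation of 0.68. Higher genes were enriched for msp (20 of 33, adjusted p = 7.13e-17), col (26 of 127, adjusted p = 7.44e-09) and the nspd and ssp sperm families (7 of 10 each). They were also enriched for puf (6 of 9, with puf-3 (2.43, adjusted p = 0.0133)), dod (5 of 8, with dod-21 (3.53, adjusted p = 0.00216)) and clec (15 of 91). Lower genes were enriched for ugt (10 of 45, adjusted p = 4.91e-07), cyp (8 of 45), ins (4 of 17) and clec (8 of 91). They were also enriched for dhs (4 of 26, with dhs-25 (-1.63, adjusted p = 0.00185)) and alh (3 of 12, with alh-9 (-1.50, adjusted p = 0.00581) and alh-5 (-1.37, adjusted p = 0.00563)). Without 1 library 8 to 13 tests passed, with 8 without OP50 replicate 3. With the score as covariate 2 passed.

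**Figure D4:**
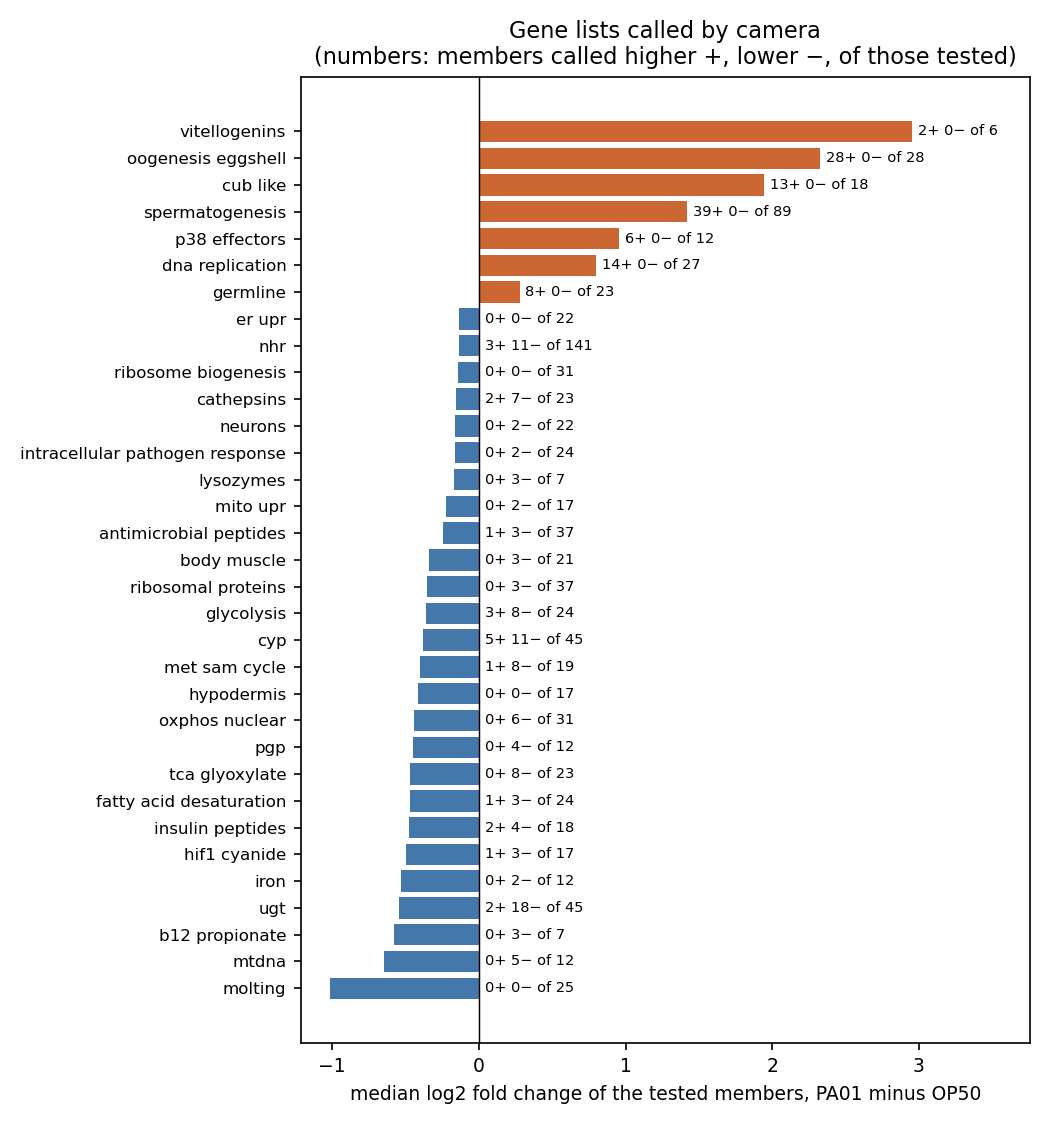
Median log2 fold change (PA01 minus OP50) of the tested members of the 33 lists that camera called, orange where the set test points higher and blue where it points lower. Numbers give the members called higher (+) and lower (−) and the members tested; the medians run from -1.01 for moulting genes to 2.96 for vitellogenins.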

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

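All tests of explanations here were chosen after the results were seen, except the count over other splits of the libraries, which was planned.

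Dixon's ratio was computed for each value with 4 libraries per group, on the log2 scale for genes. Of 230 groups of values 10 (4.35%) held a library far from the others, above Dixon's critical value for 4 values, and chance flags about 1 in 20 groups. OP50 replicate 1 stood apart for ugt-19 at 7.45 RPKM (lowest; the others 10 to 10.8) and nhr-114 at 16 RPKM (lowest; the others 22.7 to 24.2). OP50 replicate 3 stood apart for nlp-16 at 55.5 RPKM (lowest; the others 70.2 to 70.4) and cts-1 at 419 RPKM (highest; the others 298 to 312). OP50 replicate 4 stood apart for spp-17 at 1723 RPKM (lowest; the others 3148 to 3441). PA01 replicate 1 stood apart for C32H11.9 at 99.7 RPKM (lowest; the others 206 to 224), pgp-1 at 4.64 RPKM (lowest; the others 7.21 to 7.76), cpt-4 at 4.78 RPKM (lowest; the others 15.9 to 18.9) and pals-5 at 0 RPKM (lowest; the others 0.0678 to 0.0716). PA01 replicate 2 stood apart for alh-5 at 0.384 RPKM (lowest; the others 1.15 to 1.27).

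The 8 libraries can be split into 4 and 4 in 35 ways, and for each of the 7 counts 1 split, the real one, gave a count as large. For the 5 counts of genes chance is argued against by this measure, though 35 splits can give no share below 1 in 35. The splits also take all 8 libraries as exchangeable, which they would not be if libraries of the same number were pairs. The real split gave 2046 called genes against 6 in the highest other split, 1385 against 6 in the larger direction and 661 against 2 in the smaller one. At 2-fold or more it gave 741 against 6 and 284 against 2, and for the class tests that passed 13 against 0, where the other splits called too few genes for the classes to add support. The list test separates little, with 33 lists against 30 in another split and 28 to 37 in the real one without 1 library, so chance is not taken as excluded for the number of lists.

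Oocyte and eggshell genes were higher on PA01, with a median log2 fold change of 2.33 over 28 genes. The tables argue against scaling, since the median stayed at 2.17 (median SE 0.41) after quantile normalization, and against a single library, since it was at least 2.02 without any 1 library and the list stayed called. Developmental progress may account for the rise of sperm genes, whose median fell from 1.42 (median SE 0.37) to -0.12 (0.48) with the adult-stage score, which holds none of them, as a covariate. That whole score is correlated with the bacterium too (variance inflation 4.19), so a direct effect on the sperm genes is not excluded. For the oocyte and eggshell genes, with a score from yolk and cuticle genes alone, the median fell from 2.33 (0.41) to 0.97 (0.51), which leaves progress and a direct effect not to be told apart, because this score and the bacterium are correlated (variance inflation 3.03). Whether PA01 advanced the animals, OP50 plates held them back, or the groups differed in age at transfer was not tested.

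CUB-like immune genes were higher on PA01, with a median log2 fold change of 1.95 over 18 genes. With the adult-stage score as a covariate the median was 2.87 (median SE 0.35) and 12 of the 18 genes were called. This argues against developmental progress as the whole cause only if the trend within the groups also holds between them. The score is correlated with the bacterium (variance inflation 4.19), and its values in the 2 groups do not overlap. In 16 of the 18 genes the trend with the score ran against the observed change, and its cause was not tested. Scaling is argued against too, with a median of 1.78 (median SE 0.27) after quantile normalization. A response to PA01 itself may be a cause, as a hypothesis found and tested on the same data. Reads shared between neighbouring paralogs were not tested and stay open.

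Propionate shunt genes were lower on PA01, with a median log2 fold change of -0.58 over 7 genes. Scaling as the whole cause is argued against, since a common factor moves all genes alike and the list lies -0.64 (median SE 0.17) from the median of all tested genes. Developmental progress may account for part of the list, since its median went from -0.58 (median SE 0.17) to -0.18 (0.30) with the adult-stage score as a covariate, while the grown SE leaves room for a direct effect. For acdh-1 alone the change was -5.57 (SE 0.50) before and -4.64 (SE 1.02) after, with a smaller change and a larger SE, and it was no longer called (adjusted p = 0.109, against at most 0.00647 in the refits without the score), so that gene stays open.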

How the results depend on the processing

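Limma voom, protein-coding genes alone, the adult-stage score as a covariate and the enrichment of gene classes under these settings were chosen after the results were seen, and the other alternatives were planned.

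Of the 94 called genes named in the text, 67 kept their direction and call in all 16 planned refits and 0 reversed. The call was lost for 27 in at least 1 refit without a library and for 8 in another planned setting. Testing every gene above 0 ended the calls of pgp-1, rps-14, gld-1, sdha-1, perm-2, mec-12 and vit-2, quantile normalization those of rps-14 and rps-24, median-ratio scaling that of gld-1 and the replicate block that of pgp-1. Of the 14 named genes that were not called, 4 were called or turned in a planned refit. Of the 33 called lists 24 kept the call in all planned refits. The called genes numbered 1953 after median-ratio scaling, 1726 with a mean of 5 RPKM or more, 1892 and 1965 with pseudocounts of 0.1 and 0.5, 2070 without trend and robust, 2124 with limma voom and 2238 among protein-coding genes, against 2046.

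Quantile normalization gave 868 higher and 1182 lower genes, with fold changes of all genes moved by a median of -0.13, and gene gst-4 stood at -0.0092; the cause was not tested. Testing every gene above 0 in at least 1 library gave 1101 called genes, 747 higher and 354 lower, with more genes tested (27593). Without 1 library, and so with fewer samples, 619 to 2165 genes were called, 395 to 1470 higher and 224 to 695 lower, and at 2-fold or more 325 to 778 higher and 155 to 372 lower. These refits called 28 to 37 lists and passed 8 to 13 class tests. The log2 fold change of gene hsp-16.2 lay between -0.81 and 0.17 and that of gene gst-4 between -0.031 and 0.42, so both, which were not called, had no stable direction. Of the lists, 0 were called by camera with an estimated correlation (1 at an unadjusted p under 0.05) and 17 by fry.

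With the adult-stage score as a covariate limma called 116 genes (2007 at an unadjusted p under 0.05), 89 higher and 27 lower, all by 2-fold or more, and 2 class tests passed. The median SE rose from 0.198 to 0.341, since the score and the bacterium are correlated, so lost precision can be a part of the loss. The set test turned for 10 lists, with medians of -0.12 for sperm genes, -0.19 for germ cell markers, 0.045 for replication genes, -0.0050 for moulting genes, 0.32 for neuronal, 0.28 for ribosomal protein genes, 0.091 for epidermal markers (0.13 with a score without the genes it shares with that list), 0.17 for hypoxia and cyanide genes, 0.13 for endoplasmic reticulum stress genes and 0.20 for nuclear hormone receptors. Among genes, hsp-16.2 stood at 0.59, nhr-57 at 0.13 and gld-1 at -0.15.

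Numbered libraries of the groups could be pairs, which the labels do not state. After the group means were removed, libraries of the same number correlated across genes at -0.07, 0.16, 0.12 and 0.12, so 3 of 4 were above 0.1, and 2 of 4 PA01 libraries correlated best with their own number. Depths differed by up to 1.1-fold within a number and up to 2.11-fold within a group, and the adult-stage score differed by 2.62, 1.98, 2.12 and 2.58 within the numbers. These are hints of shared handling that the labels do not state. The numbers were not taken as pairs, since not every correlation passed 0.1. With the number as a block 2156 genes were called (1432 higher, 724 lower), of which 1589 are among the 2046. Among named genes and called lists it changed the calls of pgp-1 and the lysozyme list (camera adjusted p = 0.0877) and no other. A count model on the recovered reads was planned and not run, by a choice of procedure and not a limit of the data, and limma voom was run in its place. In the simulated data a gene changed by 1.5-fold was recovered in 7 of 64 cases and by 2-fold in 46 of 64, so a gene that was not called can still differ by 2-fold or more.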

Other observations

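The tests of hypotheses in this part were all chosen after the results were seen; the gene lists were fixed before the data were examined.

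Insulin-like peptide genes were among the signalling genes that moved. Of 18 tested 2 rose and 4 fell (2 and 6 adjusted over the list alone; median log2 fold change -0.47, camera adjusted p = 0.0117, or 0.512 with an estimated correlation). The peptide gene ins-33 had 24.5 ± 7.52 RPKM on OP50 and 7.94 ± 0.633 RPKM on PA01 (log2 fold change -1.46, adjusted p = 0.00696). The list call was lost when every gene above 0 was tested (camera adjusted p = 0.0965). Of 141 tested nuclear hormone receptor genes 3 rose and 11 fell (1 and 3 adjusted over the list alone; median -0.14, camera adjusted p = 0.000224, or 0.539 with an estimated correlation), led by nhr-202 with 5.98 ± 0.50 RPKM on OP50 and 1.2 ± 0.509 RPKM on PA01 (log2 fold change -1.71, adjusted p = 0.00249). Of 63 neuropeptide genes 0 rose and 1 fell, nlp-16 with 66.6 ± 7.38 RPKM on OP50 and 40.8 ± 6.26 RPKM on PA01 (log2 fold change -0.70, adjusted p = 0.0202) (0 and 0 adjusted over the list alone, 6 at an unadjusted p under 0.05; camera adjusted p = 0.174). With the adult-stage score as a covariate the medians of the insulin-like peptide and nuclear hormone receptor lists turned, to 0.33 and 0.20. The call of nlp-16 was lost without OP50 replicate 1 or PA01 replicate 2 (adjusted p up to 0.0616).

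Of 75 tested genes of the pharyngeal gland and marginal cells 7 rose and none fell (6 and 0 adjusted over the list alone; camera adjusted p = 0.222), including the glutamine-rich protein gene pqn-82 with 1.84 ± 0.672 RPKM on OP50 and 6.87 ± 2.46 RPKM on PA01 (log2 fold change 1.45, adjusted p = 0.0129). Of 46 histone genes 7 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.113), including his-58 with 2.36 ± 0.915 RPKM on OP50 and 6.50 ± 1.25 RPKM on PA01 (log2 fold change 1.2, adjusted p = 0.0150), which lost its call without OP50 replicate 3 (adjusted p = 0.0502). Of 159 F-box and MATH genes 14 rose and 9 fell (14 and 9 adjusted over the list alone; camera adjusted p = 0.954), of 19 genes of the gut brush border and junctions 2 rose (2 adjusted over the list alone; camera adjusted p = 0.418), and of 13 chitinase-like genes 1 rose (1 adjusted over the list alone; camera adjusted p = 0.949, median 0.00, mean 0.21, set test lower). Limma called 0 of 31 ribosome biogenesis genes (5 at an unadjusted p under 0.05, 1 with limma voom; median -0.14, camera adjusted p = 0.00439, or 0.512 with an estimated correlation) and 0 of 33 aminoacyl-tRNA synthetase genes (1 at an unadjusted p under 0.05, 0 with limma voom; camera adjusted p = 0.15), with 0 in both adjusted over the list alone.

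Called genes lay side by side on chromosome IV. From 12935051 to 12989365 (54.3 kb), 11 tested protein-coding genes in a row rose, from C32H11.9 through dod-21, dod-24, dod-22 and F55G11.2 to K10D11.6, with log2 fold changes of 1.00 to 4.04. In 10000 shuffled orders of the 12999 tested protein-coding genes the longest run of higher genes was 8, which gives a permutation p = 1e-04, the smallest they can give, so a chance position is argued against. A shared regulation of this region is a candidate explanation, and shared reads between neighbouring paralogs were not tested.

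On chromosome V, from 16095241 to 16105899 (10.7 kb), F22B8.7, str-7, cth-1 and argk-1, 4 neighbours in a row, fell, with log2 fold changes of -2.11, -1.29, -5.21 and -8.75. A run of 4 lower genes came up in shuffled orders with a share of 0.057, so chance could give a run of this length. The shuffles used only the direction of called genes and not the size of the change. They therefore cannot decide whether falls as large as those of cth-1 and argk-1 lie side by side by chance. A deletion of all 4 genes in the PA01 animals is argued against, since F22B8.7 kept at least 514 reads in each PA01 library. In the PA01 libraries argk-1 kept 4 to 21 reads, cth-1 13 to 52 and str-7 1 to 2, against at least 10082, 1273 and 23 on OP50. By a floor of 3 reads only str-7 could be absent in each PA01 library. Both argk-1 and cth-1 lay above that floor in each, and whether their few reads come from these genes was not tested. A smaller deletion is thus not settled.

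Bacteria differ in the vitamin B12 they supply, and B12 lowers acdh-1 and the methionine cycle genes in worms. If PA01 supplied more B12 than OP50, the methionine and S-adenosylmethionine cycle genes should be lower with and without the adult-stage score. The list used also holds genes of the canonical breakdown of propionate and genes such as cth-1, to which this prediction need not extend. Its median thus tests the prediction only in part. The list was called lower without the score (median log2 fold change -0.40, median SE 0.19) and stood at -0.014 (median SE 0.29) with it, so that B12 and developmental progress cannot be told apart for the list, because the score and the bacterium are correlated. Within the list cth-1 is an exception, at -5.21 before and -4.995 (SE 0.53, limma adjusted p = 0.0120) with the score. Progress as the whole cause of its fall is argued against only if the trend with the score within the groups also holds between them. It is also one of the 4 neighbours for which a smaller deletion is not settled, though it kept at least 13 reads in each PA01 library.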
